A study of Mus musculus with 12 samples.

How the data were processed

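RNA was measured in sorted thymocytes from mouse embryos that lack Rag1 and carry loxP-flanked Bcl6 alleles, with or without the T lineage Cre driver LckCre. There were 12 libraries in 6 groups of 2. CD25-positive cells came from unstimulated thymi. ISP cells (CD8-positive, CD4-negative) and DP cells (positive for both) came from thymi held for 2 days with 1 µg/ml of an antibody to CD3. Per the labels' protocols, RNA was extracted with a kit for small samples and libraries followed standard Illumina steps. The labels do not say whether the libraries of a group came from separate embryos or cultures. Each p-value of a single gene measures the spread between these samples, which may in part be technical. Sex-linked genes, given below, argue against repeat preparations of 1 sample in all groups but ISP KO and DP KO.

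The deposited table held RPKM values per gene, which the authors computed. BWA was the aligner and GRCm38 the genome build, per the submitters' processing notes. The counter, the annotation, tool versions and any filter are not given in the sources used here, nor is whether reads or read pairs were counted. The table had 24421 genes, of which 17114 were above 0 in at least 1 library. 27 names had the form of dates, as spreadsheet programs write some symbols, and no result here rests on them. Low values were whole multiples of a step set by the library and the gene, so reads were recovered from the steps. All 169595 values above 0 (100%) came out whole within 0.02 reads. The implied denominators ran from 9508841 reads (DP KO library 2) to 14356391 (CD25 control library 1), and 1 read in a gene of 1000 bases was worth 0.0697 to 0.105 RPKM. Recovered reads summed to between 96.4% and 101.9% of the denominator, so the authors' scaling was not to the plain total. Median-of-ratios factors computed from the values deviated from 1 by at most 2.2e-10 over 11989 genes, which means that the deposited values were already on that scale. Intervals and floors from reads cover counting error only.

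Groups followed the titles, source names and genotype labels. For 6 of the 8 anti-CD3 libraries the sequencing library name gives another population or genotype than the title, and a grouping by library name was run as an alternative. The embryonic day is 16.5 in most labels and 17.5 in the treatment protocol. Gene positions are from a GENCODE M21 annotation of GRCm38, matched by symbol.

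Tests used limma 3.58.1 in R 4.3.3 with an intensity trend, on log2(RPKM + 1), for genes with at least 1 RPKM in at least 2 libraries. Fold changes on this scale understate the change of low genes. The CD25 comparison of genotypes used its 4 libraries (10636 genes, 2 residual degrees of freedom). The others used all 12 libraries in a fit of 6 groups (11303 genes, 6 residual degrees of freedom). Genes with a Benjamini-Hochberg adjusted p under 0.05 are called. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the 31 lists that had at least 3 tested members. At the preset correlation, a camera p-value compares the genes of a list with the other genes. It is not a measure of the spread between libraries, and can be very small with 2 libraries per group. 36 lists were fixed before the data were examined, and 24 of their entries were absent from the table. No mitochondrial transcript was in the table, so that list gave no value. The erythroid, mast cell, mesenchyme and endothelium lists had fewer than 3 tested members and are given as sums only. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

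Named genes followed a rule fixed before the data were examined. It takes Bcl6 and, per comparison, up to 10 called genes with the largest rise and up to 10 with the largest fall. Their libraries must not overlap between the sides, the higher side must average at least 5 RPKM, and predicted genes are left out. With fewer than 5 called genes, the 10 with the smallest p are eligible as values. Up to 4 members per list with the smallest p, and Il2ra, Cd4, Cd8a and Cd8b1, are also eligible. The text names only part of these genes. Gh met the rule in DP and is given in the other populations because of its pattern there, which is a choice made after its values were seen.

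The procedure was tested on simulated values with known changes in the real groups. Changed genes were drawn only from those at a moderate or high mean level. Noise was independent between genes, and its spread came from the moderated fit of all 12 libraries, also for CD25. Recovery in the real data, above all of low genes and in CD25, can therefore be lower. For the DP comparison of genotypes, 88.4% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1 were recovered from 11303 genes, and 5.6% of the calls were false. For ISP these were 84.8%, 99.8% and 6.1%, and for CD25, also simulated on 11303 genes, 78.8%, 99.8% and 7.1%. Libraries of a group differed by more than counting noise in every group (chi-square per degree of freedom 3.17 to 6.79). Repeat preparations of 1 sample can do so too, so this alone does not tell whether they are separate samples. Xist was at 20.5 and 0.766 RPKM in ISP control libraries 1 and 2, and at 22.5 and 0.914 in DP control. The Y-linked gene Ddx3y was at 19.8 and 10.8 in CD25 control and at 7.61 and 18.7 in CD25 KO. These values argue against repeat preparations of 1 sample in these groups, and ISP KO and DP KO stay open.

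Other settings fixed before the data were examined were another pseudocount (0.1), no filter, a filter of 5 RPKM, the replicate number as a block, library-name groups, fits of only the groups compared, and leaving out each library in turn. Settings chosen after seeing the data were limma voom on recovered reads, a minimum of 10 recovered reads in at least 2 libraries, scaling to recovered totals, leaving out the ISP and DP control libraries numbered 2, leaving out genes on X and Y, and a minimum log2 change of 0.5.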

Results

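BCL6 is a transcriptional repressor best known from germinal centre B cells and follicular helper T cells, and the series asked what its loss does to early T cell development. Thymi came from mouse embryos that lack Rag1. Their thymocytes cannot rearrange a T cell receptor and stop at the CD25-positive stage. An antibody to CD3 mimics the missing pre-TCR signal and lets such cells move on to the CD8 immature single-positive (ISP) stage and then to the CD4 and CD8 double-positive (DP) stage. Embryos had loxP-flanked Bcl6 alleles, and LckCre-positive embryos (KO) were compared with LckCre-negative ones (control). The design therefore does not separate loss of Bcl6 from the presence of Cre. The 12 libraries were 2 control and 2 KO libraries each of unstimulated CD25-positive cells, of ISP cells and of DP cells, the last 4 groups after 2 days with 1 µg/ml of the antibody. Reads recovered from the values summed to between 9658167 and 14228673 per library, and between 10241 and 10568 genes reached 1 RPKM in each. Levels below are RPKM as mean ± SD, with n = 2 libraries per genotype and population or n = 4 per population, and adjusted p-values are from limma with Benjamini-Hochberg adjustment.

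The populations were far apart. Component 1 of a principal component analysis held 63.1% of the variance and component 2 held 24.1%. On component 1 the CD25 libraries lay between -47.5 and -46.5, the ISP libraries between -4.63 and 2.78, and the DP libraries between 42.7 and 54.1. The DP KO libraries (44.6 and 42.7) lay nearer to the ISP libraries than the DP controls did (52.8 and 54.1), and on component 2 they were at 10.8 and 6.79 against 23.1 and 21.7.

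**Figure D1:**
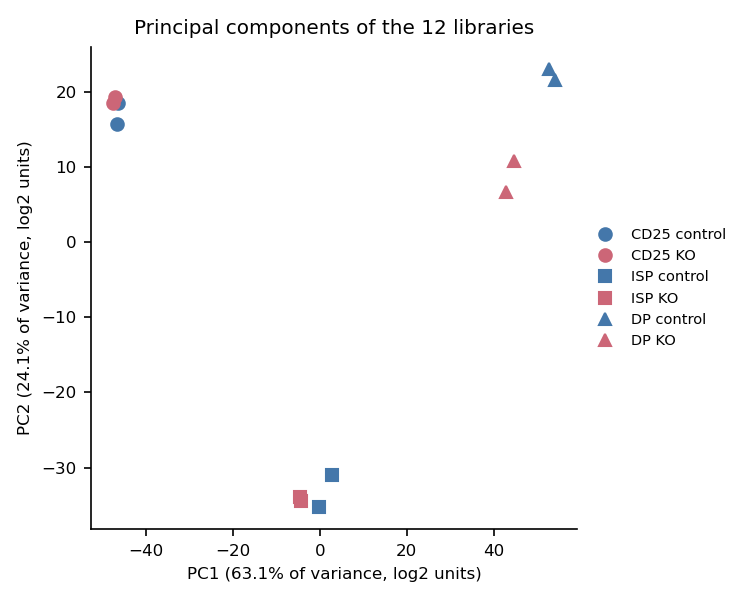
Scores of the 12 libraries on the first principal components of log2(RPKM + 1), in log2 units; shape marks the population and colour the genotype, and each symbol is 1 library. The DP KO libraries, at 44.6 and 42.7 on component 1, sit apart from the DP controls at 52.8 and 54.1.

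Bcl6 (chromosome 16, 23965052 to 23988852, GRCm38) was low in CD25 cells and rose with differentiation. It averaged 1.66 ± 0.234 RPKM in CD25 control and 1.82 ± 0.269 in CD25 KO libraries (log2 change 0.09, SE 0.16, adjusted p = 0.919). In ISP cells it averaged 11.7 ± 0.187 in control and 22.0 ± 4.39 in KO libraries, and in DP cells 71.2 ± 1.80 and 99.5 ± 16.6. The value of the whole gene was thus higher in KO than in control libraries, by 0.84 in ISP (SE 0.14, limma adjusted p = 0.0249) and by 0.47 in DP (SE 0.14, adjusted p = 0.0319). The ISP call was lost without ISP control 1 (adjusted p = 0.0917), ISP control 2 (0.155) or ISP KO 2 (0.208), and the DP call without DP control 1 (0.104), DP control 2 (0.138) or DP KO 2 (0.276). A value per gene does not show whether the loxP-flanked part is missing from the transcript, so Bcl6 checks nothing about the deletion here.

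Other genes were set beside the labels because, for 6 of the 8 anti-CD3 libraries, the sequencing library name gives another population or genotype than the title. Cd4 was at 190.6 to 344.1 RPKM in the 4 libraries titled DP and at 13.9 to 20.5 in the 4 titled ISP. The library names say control for all 4 libraries titled ISP and KO for all 4 titled DP. Reads assigned to Gh, the growth hormone gene, were found in all 6 libraries titled KO (8 to 93 reads) and in 0 of the 6 titled control, but Gh was picked because it is among the genes called by title, so this separation is no test of the titles. Against a floor of 3 reads over the control group, Gh was at least 6.40-fold higher in CD25, at least 17.9-fold in ISP and at least 56.4-fold in DP KO libraries. The median residual variance of log2(RPKM + 1) in the 8 libraries was 0.00989 in groups by title and 0.0215 in groups by library name, 2.17 times as much. Groups below follow the titles.

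The embryos of the anti-CD3 libraries also differed in sex-linked genes. Ddx3y, a gene of the Y chromosome, was at 0 to 0.0979 RPKM in the 4 anti-CD3 KO libraries. It was at 7.28 and 29.7 in ISP control, 15.7 and 56.3 in DP control, 19.8 and 10.8 in CD25 control and 7.61 and 18.7 in CD25 KO libraries. Xist, which is transcribed from the inactive X chromosome, was at 0.766 in ISP control 2 and 0.914 in DP control 2 and at 9.79 to 25.6 in the other 10 libraries. The CD25 libraries, ISP control 1 and DP control 1 thus had both Xist and Ddx3y. Each of these may hold cells of male and female embryos, so Ddx3y need not give the sex of 1 embryo.

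Markers of other tissues were summed per library in RPKM. Mast cell genes were at 24.0 to 29.5 in CD25, 10.8 and 13.2 in ISP control, 25.3 and 32.1 in ISP KO, and 0.658 to 2.47 in DP libraries. Erythroid genes were at 2.28 to 3.57 in CD25, 8.10 to 16.8 in ISP and 2.91 to 4.91 in DP, and endothelial genes at 25.4 to 29.6, 24.6 to 28.5 and 34.4 to 46.7. Mesenchymal genes were at 109.8 to 127.7 in CD25, 196.4 to 208.4 in ISP and 271.8 to 319.3 in DP, but most of this sum was Thy1, which thymocytes express (means 100.6, 193.5 and 291.1).

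**Figure D2:**
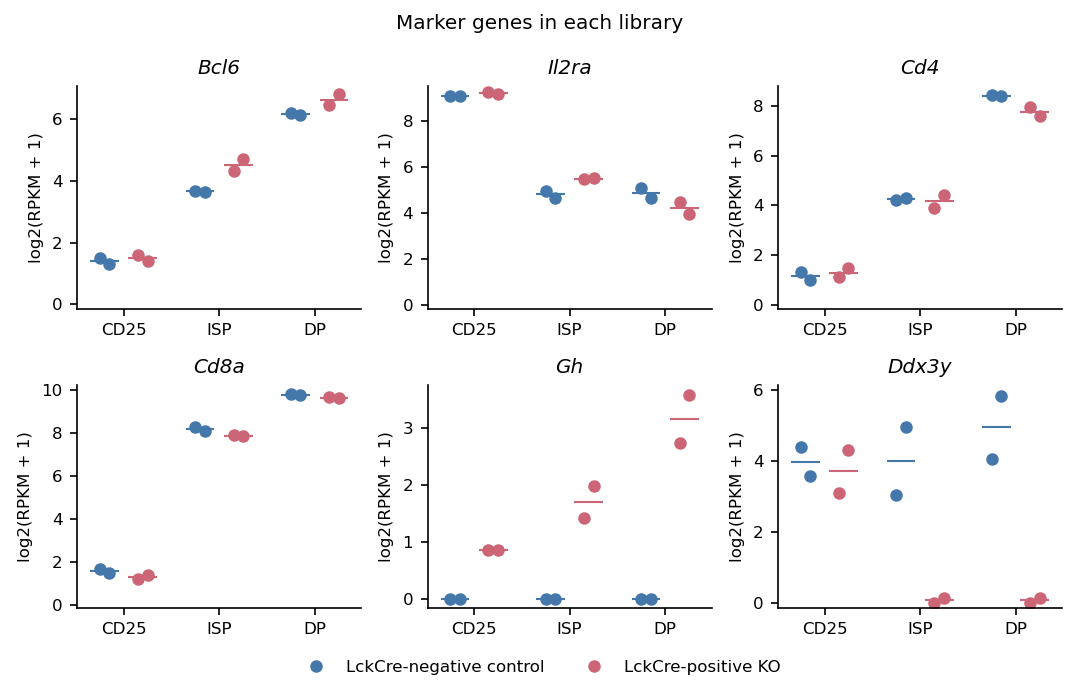
Level of 6 genes in each library as log2(RPKM + 1), by population on the horizontal axis, with control libraries in blue, KO libraries in red and a line at each group mean of 2 libraries. Cd4 separates the DP from the ISP libraries, Gh is above 0 in the 6 KO libraries alone, and Ddx3y is near 0 in the 4 anti-CD3 KO libraries.

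From CD25 to ISP cells Cd8a, a chain of the CD8 coreceptor, rose from 1.71 ± 0.358 to 258.3 ± 34.0 RPKM (151-fold, n = 4). Its partner Cd8b1 rose from 17.2 ± 1.99 to 622.9 ± 100.4. The surface receptor genes Cd2 (88.5-fold), Cd6 (67.5-fold) and Cd5 (43.2-fold) rose, as did Id3, an inhibitor of E proteins induced by receptor signals (35.8-fold), and Ikzf3 (20.5-fold). Il2ra, which encodes CD25, fell from 560.8 ± 31.0 to 35.5 ± 10.1, and Pld4 (28.8-fold), Scin (26.2-fold), Fbp1 (25.1-fold) and Mpzl2 (24.6-fold) fell with it. Bcl6 rose from 1.74 ± 0.226 to 16.9 ± 6.46 and Cd4 from 1.37 ± 0.344 to 17.6 ± 2.80. In all, 3739 genes were higher and 3489 lower in ISP, of 11303 tested, with limma adjusted p between 4.44e-15 (Cd8a) and 2.89e-09 (Scin) for the genes named so far. The ISP cells had been stimulated and held in culture and the CD25 cells had not been stimulated, so stage and treatment cannot be separated.

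Gene groups moved in this step. Of 15 genes of the T cell receptor complex 7 rose and 5 fell (the same adjusted over the list alone; camera adjusted p = 0.658, and adjusted p = 0.709 with an estimated correlation). Of 18 DP stage genes 12 rose and 5 fell (the same adjusted over the list alone; 8.26e-04, and adjusted p = 0.205 with an estimated correlation). Of 14 genes of the CD25-positive stage, 12 fell (12 adjusted over the list alone), among them Ptcra, the pre-TCR chain, from 779.9 ± 50.9 to 231.3 ± 27.3, and the Notch target Hes1 from 172.6 ± 28.1 to 25.3 ± 1.49 (camera adjusted p = 2.62e-06, and adjusted p = 0.203 with an estimated correlation). Of 22 S phase genes 21 rose (21 adjusted over the list alone; 1.63e-09, and adjusted p = 0.205 with an estimated correlation), including Rrm2 (3.11-fold) and Ccne1 (3.33-fold). All 23 genes of G2 and mitosis rose (23 adjusted over the list alone; 2.03e-10, and adjusted p = 0.205 with an estimated correlation), such as Birc5 (2.28-fold) and Mki67 (2.09-fold). Of 20 interferon response genes 19 fell and 1 rose (the same counts adjusted over the list alone; 2.71e-08, and adjusted p = 0.208 with an estimated correlation), with Oasl2 at 45.8 ± 8.96 and 4.32 ± 2.22. NK and innate lymphoid markers moved with these groups: 7 of 8 rose and 1 fell (the same adjusted over the list alone; 0.00200, and adjusted p = 0.324 with an estimated correlation), for example Ncr1 from 0.484 ± 0.285 to 8.89 ± 1.65 and Klrd1 from 1.34 ± 0.329 to 22.1 ± 5.65.

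Other companion lists also differed between CD25 and ISP. Of 5 thymic epithelium markers 3 fell and 1 rose (the same adjusted over the list alone; camera adjusted p = 0.349, and adjusted p = 0.462 with an estimated correlation; 2 rose without ISP KO 1), and 2 of 3 B lineage markers fell (2 adjusted over the list alone; 0.0990, and adjusted p = 0.240 with an estimated correlation). Of 5 sex-linked genes 4 fell (4 adjusted over the list alone; 0.144, and adjusted p = 0.444 with an estimated correlation), and of 3 long nuclear RNAs, a list kept for RNA quality, 2 fell (2 adjusted over the list alone; 0.391, and adjusted p = 0.651 with an estimated correlation).

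All 8 anti-CD3 libraries against the 4 CD25 libraries is a comparison on which titles and library names agree. It called 4028 genes higher and 4125 lower. Ckb (4.11 on the log2 scale) and Bcl6 (3.80) were higher, as were Cd8a (7.42), Cd8b1 (6.05) and Cd4 (4.92), while H19 (-5.37), an imprinted RNA of fetal tissue, and Il2ra (-4.29) were lower, each with limma adjusted p of at most 3.93e-12 (Il2ra). Of 18 DP stage genes 14 rose and 3 fell (the same adjusted over the list alone; camera adjusted p = 9.13e-07, and adjusted p = 0.177 with an estimated correlation). All 14 genes of the CD25-positive stage fell (14 adjusted over the list alone; 9.68e-07, and adjusted p = 0.164 with an estimated correlation). Beside them, 3 of 5 thymic epithelium markers fell and 1 rose (the same adjusted over the list alone; 0.611, and adjusted p = 0.699 with an estimated correlation), and 4 of 8 NK and innate lymphoid markers rose and 2 fell (the same adjusted over the list alone; 0.549, and adjusted p = 0.868 with an estimated correlation). Of 5 sex-linked genes 4 fell (4 adjusted over the list alone; 0.266, and adjusted p = 0.576 with an estimated correlation). Of 3 long nuclear RNAs 1 rose and 1 fell (1 and 2 adjusted over the list alone; 0.961, and adjusted p = 0.972 with an estimated correlation); 2 fell without CD25 control 2, CD25 KO 1, ISP KO 2 or DP KO 1.

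From ISP to DP, Cd4 rose 15.9-fold, from 17.6 ± 2.80 to 280.5 ± 73.9 RPKM (n = 4). Cd8a rose 3.20-fold, Cd8b1 3.74-fold and Bcl6 5.06-fold, to 85.4 ± 18.98. Slc6a19 (11.5-fold), Spo11 (7.56-fold) and the death receptor gene Fas (6.04-fold) also rose. Xcl1 (26.5-fold), Gzmb, which encodes granzyme B (27.1-fold), Cxcr6 (26.4-fold), Cd7 (24.6-fold), Ifitm1 (27.1-fold) and Plac8 (16.3-fold) fell. Of 13 cytotoxic and effector genes, Gzmb among them, 11 fell and 2 were not called (12 lower adjusted over the list alone; camera adjusted p = 2.01e-04, and adjusted p = 0.311 with an estimated correlation). Il2ra fell from 35.5 ± 10.1 to 23.2 ± 7.66 over both genotypes (limma adjusted p = 4.01e-04), with means of 27.0 and 28.6 in control and 44.0 and 17.8 in KO libraries. In all 4024 genes were higher and 3959 lower in DP. With groups by library name limma called 0 genes in this comparison. In the 4 libraries with the same population in title and library name it called 5109.

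S phase and biosynthesis genes were lower in DP than in ISP cells. All 22 S phase genes fell (22 adjusted over the list alone; camera adjusted p = 1.75e-10, and adjusted p = 0.311 with an estimated correlation), for example Mcm6 from 410.5 ± 12.9 to 164.2 ± 37.1 and Mcm5 from 207.3 ± 7.78 to 88.0 ± 20.1. Of 23 genes of G2 and mitosis 8 fell, 4 rose and 11 were not called (6 and 4 adjusted over the list alone; 0.466, and adjusted p = 0.833 with an estimated correlation), and the rises numbered 2 without ISP control 2, ISP KO 2 or DP KO 2 and 1 without DP control 2. This average hides opposite differences: the list's mean log2 level was 6.80 and 6.77 in ISP and 6.43 and 6.48 in DP control libraries, and 6.69 and 6.63 in ISP and 6.79 and 6.92 in DP KO libraries. All 20 ribosomal protein genes fell (20 adjusted over the list alone; 1.92e-10, and adjusted p = 0.311 with an estimated correlation), including Rpl3 (2.65-fold) and Rps18 (2.22-fold). Long nuclear RNAs went the other way, all 3 rising (3 adjusted over the list alone; median 1.28, 0.105, and adjusted p = 0.377 with an estimated correlation). All 18 genes of oxidative phosphorylation fell (18 adjusted over the list alone; 7.82e-06, and adjusted p = 0.377 with an estimated correlation), with Cycs at 38.8 ± 2.42 and 18.9 ± 4.89. So did 14 of 20 of glycolysis, while 2 rose (the same adjusted over the list alone; 6.96e-04, and adjusted p = 0.377 with an estimated correlation), with Ldha at 1384.4 ± 84.4 and 561.4 ± 40.5. Of 18 cholesterol synthesis genes 16 fell (16 adjusted over the list alone; 2.51e-05, and adjusted p = 0.311 with an estimated correlation), with Cyp51 at 71.5 ± 2.99 and 38.4 ± 9.09. Genes of the T cell receptor complex went the other way. All 15 rose (15 adjusted over the list alone; 6.96e-07, and adjusted p = 0.0397 with an estimated correlation), such as Cd247 (2.20-fold) and Rasgrp1 (2.20-fold). Of 18 DP stage genes 15 rose and 3 fell (the same adjusted over the list alone; 6.02e-06, and adjusted p = 0.262 with an estimated correlation), led by Ets2 (3.39-fold).

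Genes that BCL6 represses in B and T cells were mostly lower in DP, where Bcl6 was highest. From CD25 to ISP, where Bcl6 rose too, the list did not fall: of 22 tested, 13 rose and 7 fell (the same adjusted over the list alone; camera adjusted p = 0.374, and adjusted p = 0.709 with an estimated correlation). From ISP to DP the counts were as follows. Of 22 tested, 18 fell and 3 rose (the same adjusted over the list alone; camera adjusted p = 2.28e-04, and adjusted p = 0.318 with an estimated correlation), with Il7r at 11.0 ± 3.64 and 0.795 ± 0.269 and Ccnd2 at 33.0 ± 7.19 and 9.97 ± 7.07. All 8 NK and innate lymphoid markers fell (8 adjusted over the list alone; 2.50e-05, and adjusted p = 0.311 with an estimated correlation), with Gzma at 879.6 ± 53.9 and 132.4 ± 43.0, Tyrobp at 91.1 ± 13.2 and 10.6 ± 5.66, and Nkg7 at 131.0 ± 21.5 and 13.6 ± 1.29. Among other companion lists, 3 of 5 thymic epithelium markers rose (camera adjusted p = 0.241, and 0.377 with an estimated correlation), as did 2 of 3 B lineage markers (0.270 and 0.377). Of 17 myeloid markers 4 rose and 5 fell (0.656 and 0.833), and of 5 gamma delta markers 1 rose and 3 fell (0.508 and 0.582). These counts were the same adjusted over the list alone.

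In CD25 cells, the question was whether loss of Bcl6 acts before the stimulus. 2 genes of 10636 were called. Smim5, a small membrane protein gene (chromosome 11, 115899966 to 115906269), rose from 4.16 ± 0.328 to 25.8 ± 1.29 RPKM (6.21-fold, log2 change 2.38, SE 0.10, limma adjusted p = 1.78e-04). The histone gene Hist1h2ae fell from 60.3 ± 0.508 to 29.2 ± 4.11 (log2 change -1.03, SE 0.10, adjusted p = 0.0434). It shares sequence with other histone genes, so its value is uncertain, and its call was lost without CD25 control 1 (adjusted p = 0.113) or control 2 (0.0960). Il2ra was at 537.7 ± 0.104 in control and 583.8 ± 27.5 in KO libraries (adjusted p = 0.634), and Cd4 (1.28 ± 0.355 and 1.47 ± 0.440), Cd8a (1.96 ± 0.283 and 1.46 ± 0.247) and Cd8b1 (17.8 ± 1.58 and 16.6 ± 2.80) were not called either. At an unadjusted p under 0.05 there were 972 genes, and voom on recovered reads called 27. The count was 4 without control 1, 4 without control 2, 59 without KO 1 and 93 without KO 2, fits in which 1 side is a single library.

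Interferon response genes, which are induced by interferon and encode antiviral proteins, stood at a higher level in CD25 KO libraries as a group. None of 20 passed over all genes tested (limma adjusted p at least 0.118 for those named here), but 19 were higher adjusted over the list alone, with a median log2 change of 0.41 (camera adjusted p = 1.21e-20, and adjusted p = 0.725 with an estimated correlation). Irf7 was at 33.6 ± 1.07 and 53.02 ± 5.22, Rtp4 at 111.4 ± 3.11 and 153.4 ± 5.20, Oas1a at 9.42 ± 0.332 and 14.2 ± 0.471 and Ifit3 at 3.06 ± 0.237 and 6.20 ± 0.655 in control and KO libraries. The summed level of NK and innate lymphoid markers was 606.9 and 641.4 in control and 800.0 and 708.3 in KO libraries, with 0 of 5 called (1 higher adjusted over the list alone; 0.157, and adjusted p = 0.802 with an estimated correlation). Cd163l1, a scavenger receptor gene, was at 15.2 ± 0.338 and 23.3 ± 0.254 (adjusted p = 0.118). Irf7 and Cd163l1 were called without KO 1 (0.0322 and 0.0454), and Irf7, Cd163l1, Rtp4 and Ifit3 without KO 2 (7.60e-04, 0.0203, 0.0265 and 0.00792). In these fits the KO side is 1 library and the spread comes from the 2 controls alone.

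Ribosomal protein genes were lower as a group in CD25 KO libraries: 0 of 20 were called over all genes and 8 were lower adjusted over the list alone (median -0.17, camera adjusted p = 2.29e-13, and adjusted p = 0.725 with an estimated correlation). Rplp1 was at 676.2 ± 37.2 and 560.3 ± 17.99 and Rps18 at 978.3 ± 29.0 and 826.9 ± 3.55. For oxidative phosphorylation the counts were 0 of 18 and 1 (median -0.10, 5.46e-06, and adjusted p = 0.725 with an estimated correlation), with Ndufa1 at 357.7 ± 9.60 and 295.4 ± 7.42. For G2 and mitosis they were 0 of 23 and 0 (median -0.05, 0.00107, and adjusted p = 0.769 with an estimated correlation), with Mki67 at 40.9 ± 4.30 and 31.8 ± 0.0274.

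In ISP cells, 29 genes were higher and 11 lower in KO libraries. Lyz2, a lysozyme gene of macrophages and granulocytes, rose from 5.11 ± 2.07 to 35.1 ± 14.3 RPKM (6.87-fold, limma adjusted p = 0.0189). Lipg, an endothelial lipase gene, rose 3.11-fold (adjusted p = 0.00752), Akr1c12 2.77-fold (0.0178), the antiviral gene Ifitm3 2.36-fold (0.00641), Tnfrsf9, which encodes the costimulatory receptor 4-1BB, 2.17-fold (0.0218) and Plac8 2.06-fold (0.0181). Ly6d fell from 273.0 ± 21.7 to 153.8 ± 14.7 (adjusted p = 0.0218) and Lsp1 from 167.2 ± 4.47 to 131.6 ± 2.57 (0.0218). Cd4 (18.1 ± 0.999 and 17.2 ± 4.66), Cd8a (285.2 ± 23.5 and 231.3 ± 1.37), Cd8b1 (708.9 ± 8.15 and 536.9 ± 23.7) and Il2ra (27.0 ± 4.02 and 44.0 ± 1.02) were not called. The count was 17 without ISP control 1, 6 without control 2 and 11 without KO 2. Of the 15 called genes named for ISP, these fits lost 7, 13 and 12, and the fit without KO 1 lost 6. Lipg and Ifitm3 alone stayed called in all 12 such fits. By library name 5502 genes were called, and voom on recovered reads called 186.

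Interferon response genes were higher in ISP KO libraries too. 3 of 20 rose over all genes tested and 17 were not called, with 14 higher and 1 lower adjusted over the list alone (median 0.49, camera adjusted p = 6.65e-14, and adjusted p = 0.180 with an estimated correlation). The called members were Oas1a (1.95 ± 0.960 to 6.04 ± 0.427), Oasl2 (2.42 ± 0.0612 to 6.22 ± 0.519) and Rtp4 (32.5 ± 5.50 to 67.1 ± 5.98). Their count was 0 without ISP control 2 or KO 2, 1 without KO 1, and 7 without DP control 1 or DP control 2. Of 18 DP stage genes 0 were called and 6 were lower adjusted over the list alone (median -0.20, 1.57e-05, and adjusted p = 0.180 with an estimated correlation), with Dntt, the terminal transferase, at 186.8 ± 9.68 and 116.0 ± 24.2 and the chemokine receptor gene Ccr9 at 95.4 ± 18.5 and 62.4 ± 0.832. Dntt was called without ISP KO 1 (limma adjusted p = 0.0445), DP KO 1 (0.0280) or DP KO 2 (0.0281), and Il2ra without DP KO 1 (0.0442) or DP KO 2 (0.0438).

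Among 22 genes that BCL6 represses, 1 rose in ISP KO libraries, the chemokine gene Ccl3 (1.06 ± 0.3496 to 3.84 ± 0.798, limma adjusted p = 0.0433), and 5 were higher adjusted over the list alone (median 0.22, camera adjusted p = 5.71e-05, and adjusted p = 0.307 with an estimated correlation). The Ccl3 call was lost when any 1 of 10 libraries was left out (adjusted p 0.0516 to 0.327); it held without DP KO 1 or DP KO 2. Moving with these groups, 1 of 17 myeloid markers, Lyz2, rose (1 adjusted over the list alone; 0.00390, and adjusted p = 0.180 with an estimated correlation), and the summed level of that list was 154.2 and 212.8 in control against 237.6 and 238.1 in KO libraries. Of 5 sex-linked genes 2 fell, Eif2s3y (30.9 ± 28.4 and 0.150 ± 0.0296) and Ddx3y, and 4 were lower adjusted over the list alone (5.71e-05, and adjusted p = 0.180 with an estimated correlation). Both were lost without ISP control 2, KO 1 or KO 2, and the count was 4 without DP control 1 or DP control 2.

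In DP cells 1597 genes were higher and 879 lower in KO libraries, of 11303 tested, with a median absolute log2 change of 0.39; 96 of them changed by at least 1. Pdlim4, a gene of an actin-associated protein, rose from 20.9 ± 0.00745 to 158.0 ± 39.0 RPKM (7.55-fold, limma adjusted p = 1.67e-06). Acoxl rose 21.5-fold from 0.416 ± 0.0219 (adjusted p = 5.03e-06), the DNA methyltransferase gene Dnmt3b 6.26-fold (8.10e-05), Fam212a 5.47-fold (1.07e-04) and Ccnd2, the gene of cyclin D2, 4.11-fold from 3.90 ± 0.7002 (3.03e-05). Gh, at 0 reads in control libraries, was at 8.23 ± 3.67 in KO libraries (adjusted p = 4.82e-05). Cd4 fell from 341.0 ± 4.27 to 220.0 ± 41.7 (0.0253), Il2ra from 28.6 ± 6.11 to 17.8 ± 4.64 (0.0127), Tdrp from 10.2 ± 0.238 to 3.55 ± 0.918 (0.00145) and Podxl2 from 6.96 ± 0.296 to 2.91 ± 1.81 (0.00840). Cd8a (864.9 ± 11.2 and 786.7 ± 18.2) and Cd8b1 (2500.4 ± 7.64 and 2158.2 ± 164.0) were not called.

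The number of DP calls rested in part on single libraries. It was 1102 without DP control 1, 1177 without DP control 2 and 844 without DP KO 2, and 1022 without the ISP and DP control libraries numbered 2 together, the only libraries with Xist under 1 RPKM. The calls of Cd4 were lost without DP control 1 (limma adjusted p = 0.108), control 2 (0.0954) or KO 2 (0.224), those of Il2ra without control 1 (0.114) or KO 2 (0.130), and that of Podxl2 without control 1 (0.0538). With library-name groups 5622 genes were called.

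Cell cycle genes rose in DP KO cells. All 22 S phase genes were higher (22 adjusted over the list alone; median log2 change 0.51, camera adjusted p = 2.18e-17, and adjusted p = 0.177 with an estimated correlation). Examples are Pcna, the sliding clamp of DNA polymerase, from 215.6 ± 0.517 to 334.1 ± 36.7 and the replicative helicase genes Mcm3 (75.8 ± 5.13 to 117.4 ± 6.56) and Mcm5 (70.7 ± 3.19 to 105.2 ± 3.78), with Gins2 1.76-fold higher. Of 23 genes of G2 and mitosis 20 rose and 3 were not called (20 adjusted over the list alone; median 0.40, 1.31e-12, and adjusted p = 0.196 with an estimated correlation), including Cdk1 (72.2 ± 0.705 to 108.7 ± 11.1) and Aurka (89.5 ± 1.81 to 139.2 ± 20.03). Of 11 G1 cyclins and CDK inhibitors 3 rose and 8 were not called (3 higher and 1 lower adjusted over the list alone; 0.501, and adjusted p = 0.577 with an estimated correlation). Of the Notch list, the growth regulator Myc rose from 19.8 ± 1.48 to 38.5 ± 4.33 (limma adjusted p = 1.03e-04), with 2 of 14 members higher and 2 lower (the same adjusted over the list alone; 0.570, and adjusted p = 0.750 with an estimated correlation). In the fits without 1 library, 18 to 22 S phase genes and 14 to 20 of G2 and mitosis were called. For the Notch list 1 rose without DP control 2, KO 1 or KO 2 and 1 fell without DP control 1, control 2 or KO 2.

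Ribosomal, mitochondrial and sterol genes were higher in DP KO libraries. Of 20 ribosomal protein genes 18 rose and 2 were not called (18 adjusted over the list alone; median 0.26, camera adjusted p = 7.81e-09, and adjusted p = 0.237 with an estimated correlation), with Rpl5 1.41-fold and Rps14 1.34-fold higher. Of 3 long nuclear RNAs 1 fell (1 adjusted over the list alone; median -0.50, 0.139, and adjusted p = 0.524 with an estimated correlation), and 0 did without DP control 2 or KO 2. Of 18 oxidative phosphorylation genes 11 rose (13 adjusted over the list alone; 3.62e-07, and adjusted p = 0.297 with an estimated correlation), with Cycs, cytochrome c, 1.56-fold and Cox7a2 1.33-fold higher. Of 18 cholesterol synthesis genes 12 rose (14 adjusted over the list alone; 6.05e-07, and adjusted p = 0.196 with an estimated correlation), with Cyp51 1.502-fold and Mvd 1.55-fold higher. Without DP control 1, DP control 2 and DP KO 2 in turn, the called ribosomal genes numbered 5, 7 and 9 and those of oxidative phosphorylation 5, 7 and 6. Those of cholesterol synthesis numbered 7 without DP control 2 and 6 without KO 2.

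Interferon response genes rose in DP KO libraries as well. 15 of 20 were higher and 5 were not called (16 adjusted over the list alone; median 0.76, camera adjusted p = 3.44e-08, and adjusted p = 0.223 with an estimated correlation). Rtp4 rose from 21.1 ± 6.92 to 51.1 ± 1.44, Bst2, which encodes tetherin, from 167.3 ± 19.99 to 282.0 ± 5.39, Xaf1 from 2.82 ± 1.09 to 6.77 ± 0.611 and Oasl2 from 0.356 ± 0.0968 to 1.94 ± 0.720. The count was 7 without DP control 2 and 7 without DP KO 2. Myeloid markers moved with them: 7 of 17 rose (8 adjusted over the list alone; 0.00228, and adjusted p = 0.196 with an estimated correlation), including Lyz2 (9.26 ± 5.33 to 54.5 ± 15.1), Tyrobp (5.72 ± 0.930 to 15.5 ± 0.739) and Fcer1g (3.88 ± 1.45 to 10.7 ± 3.13). Their summed level was 49.7 and 37.7 in control and 120.3 and 138.2 in KO libraries; 4 were called without DP control 1, control 2 or KO 2 each, and Fcer1g was lost without KO 2 (limma adjusted p = 0.0602). Tyrobp and Fcer1g are also NK and innate lymphoid markers, of which 3 of 8 rose (3, with 1 lower, adjusted over the list alone; 0.242, and adjusted p = 0.653 with an estimated correlation), with a summed level of 131.1 and 114.9 in control and 185.7 and 230.0 in KO libraries. Of 5 sex-linked genes 4 fell (4 adjusted over the list alone; 0.00104, and adjusted p = 0.196 with an estimated correlation), with Ddx3y at 36.0 ± 28.7 and 0.0453 ± 0.0641 and Eif2s3y at 55.3 ± 47.2 and 0.119 ± 0.168.

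Genes of the DP stage itself were lower in DP KO libraries. Of 18 tested 11 fell and 7 were not called (13 adjusted over the list alone; median -0.31, camera adjusted p = 2.19e-08, and adjusted p = 0.177 with an estimated correlation), among them the sialyltransferase gene St6gal1 (3.43 ± 0.128 to 0.932 ± 0.119), Arpp21 (121.6 ± 0.136 to 91.9 ± 2.27), Cd2 (71.8 ± 8.50 to 50.3 ± 0.937) and Themis (150.5 ± 2.56 to 105.0 ± 9.84). The count was 5 without DP control 2 and 3 without DP KO 2, and Themis was lost without KO 2 (limma adjusted p = 0.0651). Of 15 genes of the T cell receptor complex 6 fell and 1 rose (the same adjusted over the list alone; 0.0484, and adjusted p = 0.196 with an estimated correlation). The falls numbered 3 without DP control 1, 1 without control 2 and 0 without KO 2, and the rise was lost without control 1 or KO 2.

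Of 22 genes that BCL6 represses in B and T cells, 7 rose and 1 fell in DP KO libraries (8 and 1 adjusted over the list alone; median 0.17, camera adjusted p = 0.0484, and adjusted p = 0.536 with an estimated correlation). Ccnd2, the checkpoint kinase gene Chek1 (1.69-fold, from 9.61 ± 0.294) and Selplg, which encodes a selectin ligand (1.63-fold, from 208.6 ± 12.4), rose. Klf2, a regulator of thymic exit, was lower (4.70 ± 0.945 and 2.00 ± 1.27, limma adjusted p = 0.0110). The rises numbered 3 without DP control 1 and 4 without DP KO 2, and Klf2 was lost without DP control 2 (0.0860) or KO 2 (0.0824).

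**Figure D3:**
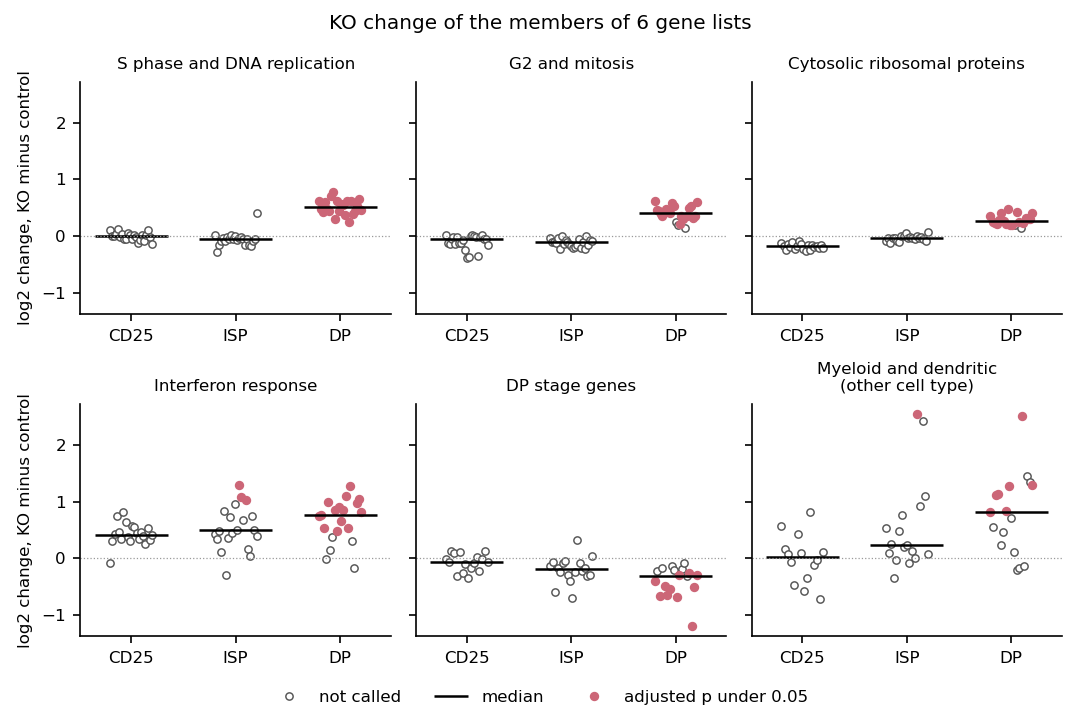
Log2 change, KO minus control, of each tested member of 6 gene lists in CD25, ISP and DP cells; filled points passed an adjusted p of 0.05 over all genes, open points did not, and the line is the list median. S phase medians were -0.06 in ISP and 0.51 in DP, while interferon medians were 0.41, 0.49 and 0.76.

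Averaged over the 3 populations, 504 genes were higher and 256 lower in KO libraries. Lyz2 (log2 change 1.96, SE 0.21, limma adjusted p = 6.56e-04), the interferon-inducible gene Ifi27l2a (0.98, SE 0.15, 0.00343) and Acsl1, an acyl-CoA synthetase gene (0.82, SE 0.09, 5.55e-04), were higher, as was Bcl6 itself (0.46, SE 0.08, 0.00656). Snhg20 (-0.30, SE 0.03, 7.06e-04), Cd8a (-0.23, SE 0.05, 0.0165) and Cd8b1 (-0.24, SE 0.06, 0.0258) were lower, and Cd4 (-0.21, SE 0.10) and Il2ra (0.05, SE 0.09) were not called. Of 20 interferon response genes 17 rose (18 adjusted over the list alone; median 0.53, camera adjusted p = 6.49e-19, and adjusted p = 0.140 with an estimated correlation). A permutation of genotype labels within populations takes the populations as independent. ISP and DP libraries may share embryos, and its p-value would then be too small. The mean of the interferon list was higher in both KO libraries than in both controls of each population, with a difference of 0.54 on the log2 scale (exact one-sided permutation p = 0.00463 over 216 assignments within populations, the smallest they can give). Myeloid markers moved with it, 4 of 17 rising (5 adjusted over the list alone; 9.06e-04, and adjusted p = 0.140 with an estimated correlation; 7 without DP KO 1). Of 8 NK and innate lymphoid markers 2 rose (3 adjusted over the list alone; camera adjusted p = 0.0605, and adjusted p = 0.577 with an estimated correlation), and 1 of 5 thymic epithelium markers rose (1 adjusted over the list alone; 0.620 and 0.661). Of 5 sex-linked genes 4 fell (4 adjusted over the list alone; 7.21e-05 and 0.140). Of 18 DP stage genes 10 fell (12 adjusted over the list alone; 5.27e-11, and adjusted p = 0.117 with an estimated correlation), and of 18 cholesterol synthesis genes 8 rose (12 adjusted over the list alone; 5.40e-09, and adjusted p = 0.151 with an estimated correlation).

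The count of calls over the 3 populations depended on single libraries and on the labels. It was 384 without CD25 KO 1, 465 without CD25 KO 2, 468 without ISP control 1, 424 without ISP KO 2, 485 without DP control 1, 384 without DP control 2, 416 without DP KO 2 and 1200 without DP KO 1. The call of Cd8b1 was lost without any of CD25 control 1, CD25 KO 1, ISP control 1, ISP control 2, ISP KO 2, DP control 1, DP control 2 or DP KO 2 (limma adjusted p 0.0571 to 0.0775). DP stage genes numbered 6 without CD25 KO 1, ISP control 2, ISP KO 2, DP control 2 or DP KO 2, and interferon genes 15 to 17 in all 12 such fits. With library-name groups 6322 genes were called.

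**Figure D4:**
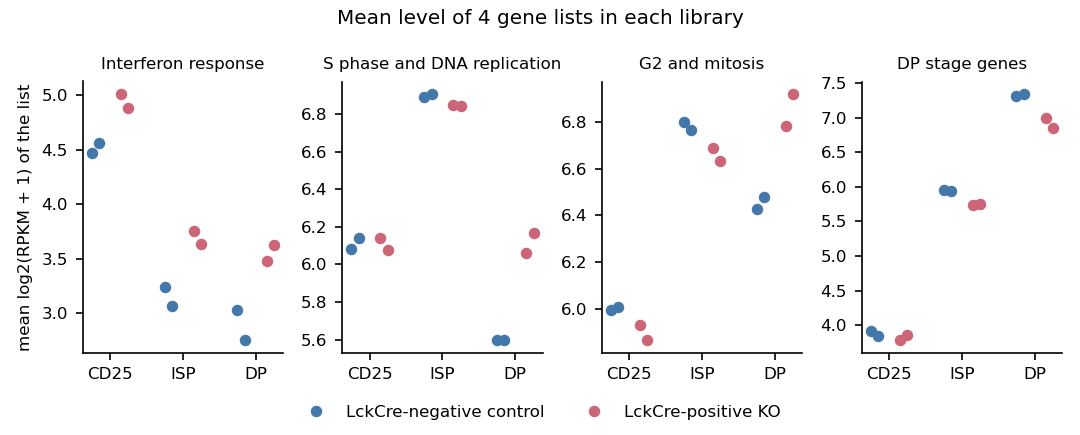
Mean log2(RPKM + 1) of the members of 4 gene lists in each library, by population, with control libraries in blue and KO libraries in red; each point is 1 library and the vertical scales differ and do not start at 0. The interferon mean is higher in KO than in control libraries of each population (5.01 and 4.88 against 4.47 and 4.56 in CD25), and the S phase mean is higher in KO libraries of DP (6.06 and 6.17 against 5.60 and 5.60).

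The KO change itself differed between populations for some genes. A test over the 3 populations called 949 genes. Between DP and CD25 the change differed for 1393 genes, higher in DP for 948 and lower for 445, and between DP and ISP for 474, higher in DP for 415 and lower for 59. Between ISP and CD25 limma called 0 genes, with 1105 at an unadjusted p under 0.05. Of 22 S phase genes, 18 had a higher KO change in DP than in ISP (21 adjusted over the list alone; camera adjusted p = 6.76e-22, and adjusted p = 0.211 with an estimated correlation), as did 17 of 23 genes of G2 and mitosis (23 adjusted over the list alone; 3.42e-19, and adjusted p = 0.226 with an estimated correlation). For the interferon list the count was 0 of 20 (0 adjusted over the list alone; median difference 0.13, 0.341, and adjusted p = 0.767 with an estimated correlation). Between DP and CD25, 2 of 20 interferon genes had a higher KO change in DP (4 higher and 2 lower adjusted over the list alone; median difference 0.27, camera adjusted p = 0.214, and adjusted p = 0.729 with an estimated correlation). The count of 949 was 427 without CD25 KO 1, 522 without CD25 KO 2, 632 without ISP KO 2, 262 without DP control 1, 320 without DP control 2 and 310 without DP KO 2, and 3077 with library-name groups.

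Genes called in ISP overlapped those called in DP. Of 29 genes higher in ISP KO libraries 18 were also higher in DP KO libraries, of 11 lower in ISP 3 were lower in DP, and 0 genes were called in opposite directions. Both sets of calls share 1 estimate of the spread per gene, and low Xist in both control libraries numbered 2 leaves open that they share embryos, so no test of the overlap is given.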

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

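The tests on cells of the ISP gate, on embryo sex and on passage from ISP to DP were chosen after the result was seen, and the regroupings of libraries before it.

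The KO change differed between populations for 949 genes, between DP and CD25 for 1393 and between DP and ISP for 474. The change in DP minus that in ISP was 2.24 for Pdlim4 (SE 0.20, limma adjusted p = 0.00115), 1.33 for Ccnd2, the gene of cyclin D2 (SE 0.19, 0.00812), 0.74 for the growth regulator Myc (SE 0.11, 0.0101), 0.68 for the helicase gene Mcm3 (SE 0.10, 0.00812) and 0.69 for the mitotic kinase gene Cdk1 (SE 0.10, 0.00812). For Il2ra, which encodes CD25, it was -1.35 (SE 0.22, 0.0122), with a change of 0.69 in ISP, where it was not called, and -0.66 in DP. The number 949 was 366 with no filter on low values, 79 without the ISP and DP control libraries numbered 2, and 262 to 1359 with 1 library left out.

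Higher S phase genes in DP KO libraries could come from ISP cells inside the DP gate, from embryo sex, or from DP KO cells that left the ISP pattern later. ISP cells with the average profile of the ISP libraries are excluded as the whole cause: 170 genes much higher in ISP gained a median of 8.77% of the ISP to DP difference (quartiles 1.38 to 15.3), against 25.7% for S phase genes (22.8 to 41.7). A smaller share of such cells, or ISP cells whose profile differs from that average, stays open. Sex acting alike in ISP and DP is excluded, because the S phase median was -0.0575 in ISP, where the sex-linked genes differed too, and 0.51 in DP. Sex acting in DP alone is not covered by this and stays open. The S phase mean was 5.60 in both DP controls, with Ddx3y at 15.7 and 56.3, but each is a single library. For slower passage the tables cannot tell: KO changes in DP correlated across genes with ISP minus DP at r = 0.447 and 0.494 with control libraries split, and of calls made without DP control 2, 835 of 886 higher and 261 of 289 lower genes ran toward ISP, where 49.5% of all genes are higher, but ISP cells in the gate would give such a correlation too, and the 8.77% goes against an even delay. The G2 and mitosis list, however, reached the ISP level. Its mean log2 level was 6.43 and 6.48 in DP control and 6.79 and 6.92 in DP KO libraries. It was 6.80 and 6.77 in ISP control and 6.69 and 6.63 in ISP KO libraries. A partial ISP pattern would stay below that level. These values argue against slower passage or average ISP cells as the whole cause for this list, but do not cover S phase genes. A direct effect of BCL6 on Ccnd2, Myc or the cell cycle, and litter or day of the experiment, which the labels do not give, remain open. Control embryos had no Cre, so an effect of BCL6 loss cannot be told apart from one of Cre.

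Regrouping the libraries asks only whether chance can be excluded. For KO against control over the 3 populations, 3 of 100 assignments called as many genes, the real one with 760 and a highest other of 1229. Few assignments called as many, but the real one did not call the most. Both others kept the ISP and DP libraries grouped by genotype and changed the CD25 libraries' place. The count thus rests on the ISP and DP grouping, and no conclusion on chance is drawn from it. The other comparisons were fitted here with the grouping alone, so their counts differ from those of the main fit. In them 1 grouping, the real one, called as many: 4724 genes with a highest other of 4 for anti-CD3 against CD25, 6915 with 0 for ISP against CD25, and 7090 with 1 for DP against ISP.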

How the results depend on the processing

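Settings tied to library names, pseudocount, filters, the replicate block and leaving out single libraries were chosen before the data were seen, and voom, recovered reads, the control libraries numbered 2, genes on X and Y and a minimum change of 0.5 after. Calls in CD25 KO, 2 at first, were 1 with a pseudocount of 0.1, 1 with no filter, 9 with all 12 libraries in the fit, 0 with those grouped by library name, 27 with voom, and 4–93 with 1 library left out. In ISP KO, 40 became 8 with no filter, 67 at 5 RPKM, 186 with voom, 78 with at least 10 reads, 12 without the control libraries numbered 2, 5502 by library name and 6–56 with 1 library left out. In DP KO, 2476 became 1022 without the control libraries numbered 2, 703 with a change of at least 0.5, 5622 by library name and 844–2604. Over the 3 populations, 760 became 417, 282, 117 and 6322 with no filter, without those controls, at 0.5 and by library name, 0 in the 8 libraries with 1 genotype in title and library name, and 384–1200. Those 8 hold no ISP KO and no DP control library, so they mix genotype with population and test nothing about genotype. The 949 genes of the interaction became 366, 79 and 3077 with no filter, without those controls and by library name, and 262–1359. At 0.5 the 8153 of anti-CD3 against CD25 became 3573 (7467–8099 with 1 library left out), the 7228 of ISP against CD25 became 3139 (6637–7348), and the 7983 of DP against ISP became 4061 (7498–8035), 5109 in 4 libraries with 1 population in title and library name, and 0 by library name. Lists called by camera fell from 7, 11, 12, 10, 11 and 14 to 0 with an estimated correlation (CD25, ISP, DP, 3 populations, anti-CD3, ISP against CD25), and for DP against ISP from 10 to 1, and to 5 by library name. Where counts moved, the cause was not tested, except by library name, where the construction sets DP-titled against ISP-titled libraries as genotypes and libraries of both titles on each side of DP against ISP.

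With the replicate block the counts were 3, 42, 2503, 808, 1013, 8151, 7235 and 7988, in the order above. Residuals of same-numbered libraries correlated at -0.0658 to 0.125 over 15 pairs of groups, 1 above 0.1. That pair was ISP control with DP control (0.0922 without genes on X and Y), whose libraries numbered 2 both had low Xist. With 2 numbers per group these correlations are not treated as pairing, and shared embryos of ISP and DP controls stay open. The planned median-of-ratios scaling is void because the factors are 1. The planned tests for counts were not run because the deposited values were not counts, although reads could be recovered from them. Scaling to recovered totals took the share of higher genes among calls from 64.5% to 57.0% in DP KO, from 49.4% to 43.7% in anti-CD3 against CD25 and from 51.7% to 43.8% in ISP against CD25.

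The label check, a median residual variance of 0.00989 by title, was 0.0215 by library name. For the genes named in the text, 123 called results had 2820 values in settings other than library names, with 0 reversed and 114 no longer called. By library name the log2 change reversed in ISP KO for Lipg -1.37, Akr1c12 -1.07, Oas1a -0.74, Ifitm3 -1.54, Oasl2 -1.27, Plac8 -4.22, Rtp4 -0.52, Tnfrsf9 -2.62, Ccl3 -0.86, Eif2s3y 0.43, Ddx3y 0.44, Ly6d 0.13, Lsp1 0.95, Dntt 1.15, Ccr9 1.71, Il2ra -0.77, Cd4 3.63, Cd8a 1.71 and Cd8b1 1.89. In DP KO it reversed for Pdlim4 -1.45, Fam212a -1.01, Dnmt3b -1.50, Ccnd2 -1.71, Ddx3y 0.51, Eif2s3y 0.38, Tdrp 1.62, Podxl2 1.08, Cd4 4.15, Cd8a 1.65, Cd8b1 1.93, Mcm5 -1.29, Gins2 -1.55, Mcm3 -1.41, Pcna -0.96, Cdk1 -0.39, Aurka -0.23, Rpl5 -1.24, Rps14 -0.66, Cycs -1.002, Cox7a2 -0.42, Cyp51 -0.89, Mvd -0.50, Rtp4 -0.49, Xaf1 -0.38, Oasl2 -1.39, Arpp21 1.13, Themis 1.30, Chek1 -1.23, Myc -2.33, Tyrobp -2.95 and Fcer1g -2.73. Over the 3 populations it reversed for Snhg20 0.10, Cd8a 1.03, Cd8b1 1.24, Il2ra -0.36 and Cd4 2.63, and in the 8 libraries, where the ISP to DP difference enters, for Cd8a 0.60, Cd8b1 0.75, Il2ra -0.24 and Cd4 1.82. In DP against ISP it reversed for Bcl6 -0.16, Cd4 -0.0557, Il2ra 0.29, Fas -0.01, Ifitm1 0.0335, Xcl1 0.29, Gzmb 0.43, Cd7 0.15, Plac8 0.0759 and Nkg7 0.0413.

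Reversals with a library left out concerned genes that were not called. They were Bcl6 in CD25 without control 2 (-0.0049) or KO 1 (-0.012, highest 0.18 without KO 2), Cd4 in CD25 without control 2 (-0.05) or KO 2 (-0.07), Cd8b1 in CD25 without KO 1 (0.0567, lowest -0.27 without KO 2), Cd4 in ISP without ISP KO 1 (0.17), and Il2ra over the 3 populations without DP control 2 (-0.022), DP KO 1 (-0.036), ISP control 2 (-0.00047) or the control libraries numbered 2 (-0.071).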

Other observations

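The tests on Lyz2 and Gh were chosen after the result was seen, and those on interferon response genes before it.

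Interferon response genes as a list were higher in KO libraries (0, 3 and 15 of 20 called in CD25, ISP and DP; adjusted p = 0.725, 0.180 and 0.223 with an estimated correlation), and Lyz2 was higher in ISP and DP, which could come from myeloid cells, embryo sex, a difference between litters, or loss of BCL6 in thymocytes. For myeloid cells the tables cannot tell: the summed interferon rise in RPKM was 3.05 times that of the myeloid list in DP, 3.79 in ISP and 20.7 in CD25, but the bound set beforehand took myeloid cells to hold no more interferon than marker transcripts, which no library of such cells measures. Embryo sex as the whole cause is excluded in CD25, where KO and control libraries paired by Ddx3y level differed by 0.409 and 0.454 on the log2 scale, against at most 0.132 within a genotype. In ISP and DP the KO libraries had almost no Ddx3y, so sex and genotype cannot be told apart there. The library with less Ddx3y had the higher interferon mean in CD25 control (4.56 against 4.473), CD25 KO (5.014 against 4.882), ISP control (3.238 against 3.071) and DP control (3.035 against 2.753). For Lyz2, macrophages like those in control libraries are excluded in ISP, where the fold of complement C1q genes was 14.5% of that of Lyz2, and in DP the 48.6% cannot tell. Loss of repression by BCL6 was not tested and cannot be told apart from the presence of Cre. Litter or infection status, which the labels do not give, stays open.

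Reads of Gh in 6 of 6 KO and 0 of 6 control libraries could come from pituitary RNA or from growth hormone sequence in the Cre transgene, since Lck promoter constructs often carry part of a growth hormone gene. Pituitary RNA is hard to square with 159 reads of 4 other pituitary hormone genes in KO libraries and 156 in control libraries, beside 225 Gh reads in KO libraries alone. The transgene fits, though its sequence was not at hand. The reads would then mark the Cre transgene, but Gh was picked from genes called by title, and they do not show that Bcl6 was deleted.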
